A study of Mus musculus with 5 samples.

How the data were processed

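Total RNA of 5 samples of mouse hepatobiliary organoids was isolated with a PicoPure kit and made into stranded, ribosomal-RNA-depleted libraries, per the labels' protocols. The groups, from the titles, are organoids alone (2 samples, passage 1) and organoids co-cultured with liver endothelial cells (3 samples, passage 8), all at day 10. The submitters' processing notes name Trimmomatic 0.38, FastQC 0.11.7, HISAT2 2.1.0, Bowtie2 2.3.4.1 and StringTie 2.1.3b, and the builds GRCh37 and mm10, with no roles; which tool counted the reads, whether it used strand, and the annotation are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty.

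The authors deposited 1 table for 4 libraries with estimated counts per Ensembl gene, per the file headers and values. Its 73925 rows hold 52029 genes, because a gene with several transcript biotypes is repeated with identical values; 1 row was kept per gene. A count that was not whole occurred in 31.7% of the 28691 genes with a count above 0, and estimated counts were rounded before testing. Its columns name the group and a library number (M11 and M12 alone; M9 and M10 co-culture) but no sample of the group. The table's other measures were not used here. For the third co-culture library the authors deposited a separate table of whole-number counts per RefSeq gene, per the file headers; its column carries another library number than the record it was filed under, and the sample was taken from the record. It was joined by gene symbol for 30882 genes, which hold 97.8% of its counts.

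The 4 libraries of the shared table were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, robust quasi-likelihood fit and test, and Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.07. Standard errors are the absolute log2 fold change divided by the square root of F. CPM, counts scaled to a common library size, are TMM-scaled, but the sums over endothelial genes are per total count. They use the 4 libraries, except where a value of the third co-culture library is given, which is scaled over all 5 libraries with prior count 2 for log2 differences. That library has no replicate in its table and its differences have no test. Its log2 differences, and genes called above or below the organoids alone by them, are against the mean log2 CPM of M11 and M12. Where a group had 3 counts or fewer, a ratio of counts per total with an exact binomial 95% interval is given, or with 0 counts a bound from a floor of 3 counts over the group; these cover counting error only. Gene lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 28 lists with enough tested genes of the 29 fixed. The tests, the alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule took the 10 largest called increases and decreases with a mean log2 CPM of at least 3, a proper symbol and groups that do not overlap; up to 4 called members of each list by smallest p, or the 2 most abundant where none was called; and Pecam1, Cdh5, Stab2, Alb, Epcam, Krt19, Sox9, Lgr5 and Mki67. Not every gene it took is printed.

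The edgeR step was tested on simulated counts for 15899 genes, 200 of them, all with a mean above 50 counts, changed: it recovered 38% of genes changed 2-fold, 82% at 4-fold, 96% at 8-fold and 100% at 16-fold, with 17 false calls among 175. On the same counts DESeq2 made 50 false calls among 220 and limma-voom 17 among 172. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other low-count filters, each library left out, and all 5 libraries. Left-out fits leave 1 library in an arm, which is then assumed to vary like the other group. Gene positions are from GENCODE M21 (GRCm38), matched on Ensembl ID; all 58 genes looked up were found. A gene's value covers its whole count, so exons and UTRs are not told apart.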

Results

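Hepatobiliary organoids are self-renewing epithelial cultures, here grown from primary wild-type mouse liver stem/progenitor cells. Total RNA was sequenced from organoids cultured alone and from organoids cultured together with liver endothelial cells, to look for pathways by which the endothelium acts on survival and proliferation of the progenitors. There were 2 libraries of organoids alone and 3 of co-cultures, all at day 10. The organoids alone were at passage 1 and the co-cultures at passage 8, so each difference given here is one between organoids alone at passage 1 and co-cultures at passage 8. The libraries of organoids alone, M11 and M12, held 26466739 and 29195328 counts. The co-culture libraries M9 and M10 held 33881617 and 35878241, and these 4 libraries share one deposited table. The third co-culture library, in a table of its own with another gene annotation, held 58853737 counts. Mitochondrially encoded genes took 2.6% of counts in M11, 2.1% in M12, 2.2% in M9, 2.1% in M10 and 5.9% in the third co-culture library. The labels do not say whether libraries of one group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The 2 libraries of each group differed by more than counting noise, with a chi-square per degree of freedom of 37.1 for the pair alone and 103.2 for M9 and M10.

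In M9 and M10, 11 of 23 glycolysis and hypoxia genes, the biliary keratins Krt7 and Krt19, and Gpa33, Myo7b and Lgals4 were higher than in the organoids alone, though no gene list was called with an estimated correlation (smallest adjusted p = 0.681). The chemokines Cxcl1 and Cxcl5, the plasma proteins Alb, Hp and Trf, and the mesenchymal genes Rgs5, Col3a1 and Col6a3 were lower. Against the organoids alone, the third co-culture library went the other way for Krt7, Krt19, Alb and Trf. Only 6 of the 23 glycolysis and hypoxia genes were higher there. It went the same way for Gpa33, Myo7b, Lgals4, Cxcl1, Cxcl5, Hp, Rgs5, Col3a1 and Col6a3. With 2 libraries per group, camera with an estimated correlation passed 0 of 28 lists even at an unadjusted p under 0.05. Its adjusted p of 0.681 is shared by many lists through the adjustment, and the smallest unadjusted p was 0.08 (squamous list). Whether camera with an estimated correlation would call a truly shifted list here was not tested, so a missing call cannot decide against a list. Which correlation is nearer was not tested either. Of 15899 genes tested, 356 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 158 of them higher and 198 lower in co-culture. At least 2-fold changes made up 346 of the calls, 148 higher and 198 lower, and the smallest called change was 0.85 on the log2 scale. At an unadjusted p under 0.05 there were 2779 genes. Single libraries moved the count strongly: edgeR called 50 genes without M11, 0 without M12 (1438 at an unadjusted p under 0.05), 2619 without M9 and 1114 without M10, while the sign of all 356 genes was kept in each of these 4 fits. DESeq2 called 1314 genes and limma-voom 285 on all 4 libraries, and edgeR called 2 with the third co-culture library added, Trpv4 and Nos2, both lower and both named after their values were seen. On simulated counts DESeq2 made 50 false calls among 220 and edgeR 17 among 175, both above a share of 0.05. That gap in calls is far smaller than 1314 against 356, and without a low-count filter edgeR itself called 1404. What makes up DESeq2's larger count was not tested.

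At a mean log2 CPM of at least 3 and with no overlap between groups, the largest called increases included those of Lypd8, AA467197, Slc16a3, Gpa33, Ankrd37, Myo7b, Ak4, Kbtbd11 and Muc3. Gpa33, a surface antigen of intestinal epithelium, rose from 3.77 ± 0.45 to 99.2 ± 0.089 CPM (counts scaled to a common library size; SD, n = 2 each), a log2 fold change of 4.72 with a standard error of 0.20 (adjusted p = 0.00387, edgeR). This gene (ENSMUSG00000000544) is protein coding and lies on the plus strand of chromosome 1 from 166130238 to 166166510 in GRCm38. Myo7b, a myosin of the microvillar brush border, rose by 4.61 ± 0.56 (log2, SE; adjusted p = 0.0244), from 2.37 to 58.1 CPM; it (ENSMUSG00000024388) spans 31959234 to 32036961 on the minus strand of chromosome 18. Slc16a3, a lactate exporter, rose by 5.76 ± 0.66 (adjusted p = 0.0216), with 75.6 CPM in M9 and 257 in M10 against 2.86 and 3.26 in the organoids alone; it (ENSMUSG00000025161) spans 120948480 to 120960868 on the plus strand of chromosome 11. Lypd8 differed between the co-culture libraries, at 37.1 CPM in M9 and 5.97 in M10. In the third co-culture library Lypd8, Gpa33, Ankrd37, Myo7b and Kbtbd11 were above the organoids alone by 6.88, 3.59, 1.56, 4.08 and 3.19 on the log2 scale, whereas AA467197, Slc16a3, Ak4 and Muc3 were lower by log2 differences of -1.23, -1.20, -2.50 and -0.62. Calls of Lypd8, AA467197, Slc16a3, Ankrd37, Ak4 and Muc3 were lost without M11, those of all the genes named here without M12, and that of Myo7b also without M9 or M10. Limma-voom did not call Lypd8, AA467197, Slc16a3, Ak4 and Muc3, and without a low-count filter edgeR did not call Lypd8, AA467197, Slc16a3 and Myo7b. Folds that leaned on 1 library were those of Lypd8 (7.26 without M11, 9.05 without M12, 6.03 without M9, 8.65 without M10), Myo7b (3.99 without M11, 5.76 without M12), AA467197 (6.76 without M9, 4.57 without M10), Slc16a3 (6.40 and 4.63), Muc3 (4.75 and 3.04), Ankrd37 (4.11 without M10) and Ak4 (3.52 without M10).

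At the same level and without overlap, the 10 largest called decreases were those of Hp, Alb, Bdkrb2, Rassf4, St8sia6, Cdh2, C3, Cyfip2, Fgfr1 and Stox2. St8sia6, a sialyltransferase, fell from 59.4 ± 9.31 to 0.903 ± 0.024 CPM (SD, n = 2 each), a log2 fold change of -6.03 with a standard error of 0.25 (adjusted p = 0.00387, edgeR). Cdh2, which encodes N-cadherin, changed by -5.81 ± 0.34 (adjusted p = 0.0069), from 22.2 to 0.394 CPM; it (ENSMUSG00000024304) spans 16588877 to 16809246 on the minus strand of chromosome 18. Fgfr1, a fibroblast growth factor receptor, changed by -5.13 ± 0.38 (adjusted p = 0.00797), and it (ENSMUSG00000031565) spans 25513654 to 25575718 on the plus strand of chromosome 8. C3, the central complement component, was at 1332 and 2315 CPM in M11 and M12 and at 63.2 and 13.9 CPM in M9 and M10, a change of -5.57 ± 0.81 (adjusted p = 0.0354). The third co-culture library lay below the mean log2 CPM of the organoids alone for 9 of these 10 genes, Alb (1.14) being the exception. Its falls were far smaller than those of M9 and M10 for Hp (-1.27), Bdkrb2 (-1.29), Rassf4 (-1.89), C3 (-1.55) and Cyfip2 (-1.645). Hp, at 19.2 CPM there, was above M11 at 15.9 CPM. St8sia6, Cdh2, Fgfr1 and Stox2 were at -7.88, -4.80, -4.10 and -5.06. M11 and M12 serve both comparisons, which are therefore not independent. Without M11 the calls of C3 and Stox2 were lost, without M12 those of all 10, and without M9 or M10 those of Hp, Alb and Bdkrb2. Limma-voom did not call Hp, Alb and Bdkrb2, and without a low-count filter edgeR did not call C3 and Hp. C3 was at -7.03 without M9 and -4.85 without M10, Stox2 at -6.26 and -4.46, and Bdkrb2 at -6.33 without M12.

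Of the 23 glycolysis and hypoxia genes tested, 11 rose in M9 and M10, 12 did not pass and none fell, and all 23 had a positive fold change. With adjustment over the list alone, 21 rose. Ldha, which makes lactate from pyruvate, rose from 527 ± 9.39 to 1729.6 ± 212.7 CPM (SD, n = 2 each), a log2 fold change of 1.72 ± 0.16 (SE; adjusted p = 0.0162, edgeR). Pgk1, a glycolytic kinase, rose by 2.16 ± 0.23 (adjusted p = 0.0203), and Ankrd37, a hypoxia-inducible gene, by 4.70 ± 0.50 (adjusted p = 0.0202). The median over the list was 1.72, and camera with its preset correlation gave an adjusted p of 4.82e-19, against an adjusted p = 0.681 with an estimated correlation. In the third co-culture library only 6 of the 23 genes lay above the organoids alone and the median was -0.38; Ldha, Pgk1 and Slc16a3 were below them by log2 differences of -1.28, -1.15 and -1.20. The number that rose was 0 without M11, 0 without M12, 21 without M9, 17 without M10 and 0 with all 5 libraries; in those with 0, adjusted over the list alone, edgeR gave 19, 18 and 0. DESeq2 called 19 and limma-voom 8.

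Of 17 inflammatory and acute phase genes tested, 4 fell, 13 did not pass and none rose. These were Cxcl1 and Cxcl5, which attract neutrophils, Lcn2, an iron-siderophore-binding protein of the acute phase, and the adhesion molecule Icam1. Cxcl1 fell from 463 ± 41.7 to 72.4 ± 5.16 CPM (SD, n = 2 each), a log2 fold change of -2.68 ± 0.16 (SE; adjusted p = 0.0069, edgeR). Cxcl5 changed by -1.69 ± 0.18 (adjusted p = 0.0197), Lcn2 by -3.09 ± 0.37 (adjusted p = 0.0231) and Icam1 by -1.32 ± 0.17 (adjusted p = 0.0275). The list's median was -1.32 and, adjusted over the list alone, 7 fell and 1 rose, while camera gave an adjusted p of 9.02e-06 and an adjusted p = 0.681 with an estimated correlation. Over this list the third co-culture library had a median of -0.85, with Cxcl1 at -2.28 and Icam1 at -0.12. Of 6 macrophage genes tested, 3 had a positive and 3 a negative fold change, none rose and 2 fell: Cd14 by -1.22 ± 0.18 (adjusted p = 0.0349), and Lyz2, a lysozyme of myeloid cells, which was at 8.81 and 2.20 CPM in M11 and M12 and at 0.119 and 0.057 CPM in M9 and M10 (adjusted p = 0.0451); adjusted over the list alone, 3 fell. The inflammatory genes that fell numbered 1 without M11, 0 without M12, 11 without M9, 6 without M10 and 0 with all 5 libraries, and the macrophage genes 0, 0, 1, 2 and 0. In addition 1 inflammatory gene rose without M9 and 1 without M10, and 1 macrophage gene without M9. The inflammatory median was -0.64 without M10. Lyz2, at -4.58 without M11 and -6.59 without M12, was not called without M9 or M10 or by limma-voom.

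**Figure D1:**
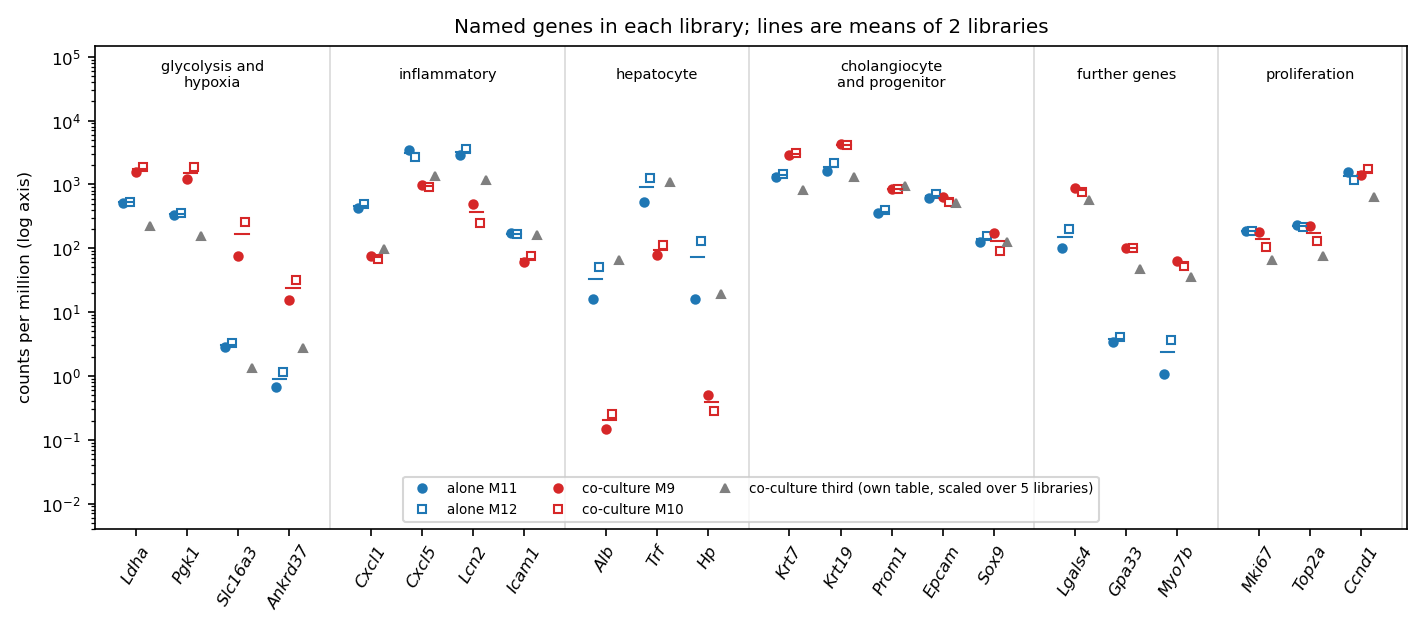
CPM (log axis) of named genes in each library: blue marks are organoids alone (M11, M12), red marks co-cultures (M9, M10), short lines their means, and grey triangles the third co-culture library, scaled over 5 libraries. Ldha stands at 1579 and 1880.02 CPM in M9 and M10 and at 223 CPM in the third co-culture library, below both libraries of organoids alone at 520.1 and 533 CPM.

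Of 30 hepatocyte genes listed, 14 were tested and 3 of these fell: Alb (serum albumin), Trf (transferrin) and Hp (haptoglobin). Alb was at 16.2 and 50.5 CPM in the organoids alone and at 0.148 and 0.257 CPM in M9 and M10, a log2 fold change of -7.33 ± 0.76 (SE; adjusted p = 0.0186, edgeR). Trf was at 528 and 1278 CPM alone and at 77.6 and 112 CPM in co-culture, a change of -3.25 ± 0.46 (adjusted p = 0.0345), and Hp at 15.9 and 128.9 against 0.505 and 0.286 CPM, a change of -7.51 ± 1.22 (adjusted p = 0.046). Without M12 these were -6.29 for Alb, -2.48 for Trf and -5.32 for Hp, and without M11 -7.92 for Alb and -8.33 for Hp. None of the 14 rose and 11 did not pass, and adjusted over the list alone, 5 fell and 3 rose. Among the 11, Fga had 790 counts in M11 and M12 together and 1 in M9 and M10, a ratio of 990 (95% counting interval from 177). Fgb had 874 against 1, a ratio of 1095 (from 196). The fold change was positive for 4 of the 14, and the mean was -2.54, or -2.24 with 2 genes at their bounds. The median over the list was -0.63, and camera gave an adjusted p of 0.0339, which became an adjusted p = 0.681 with an estimated correlation. Against the mean log2 CPM of the organoids alone, the third co-culture library was at 1.14 for Alb, 0.39 for Trf and -1.27 for Hp. Its Trf (1103 CPM) and Hp (19.2 CPM) lay between the values of M11 and M12. The number that fell was 6 without M11, 0 without M12, 1 without M9, 1 without M10 and 0 with all 5 libraries, where camera gave an adjusted p of 0.166; 2 rose without M9 and 1 without M10. The calls of Alb, Trf and Hp were each lost without M12, without M9 and without M10, so the 1 gene that fell without M9 and the 1 without M10 are none of these. The median was -1.47 without M11 and -2.35 without M9. DESeq2 called 2 higher and 5 lower and limma-voom 1 lower. Limma-voom did not call Alb and Hp, nor edgeR without a low-count filter Trf and Hp.

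Of 21 cholangiocyte and progenitor genes tested, 3 rose and none fell: Prom1, a surface protein of progenitors, by 1.19 ± 0.15 (log2, SE; adjusted p = 0.0264, edgeR), Krt7 by 1.11 ± 0.15 (adjusted p = 0.0303) and Krt19 by 1.15 ± 0.18 (adjusted p = 0.0436). Krt19 was at 1896 ± 351.6 CPM alone and 4193 ± 109 CPM in co-culture (SD, n = 2 each); in the third co-culture library it was at 1288 CPM and Krt7 at 825 CPM, both below the organoids alone, while Prom1 was at 947 CPM. The other 18 did not pass, among them Epcam, a surface marker of biliary epithelium, at -0.19 ± 0.17 (adjusted p = 0.635) and Sox9, a transcription factor of biliary progenitors, at -0.07 ± 0.31 (adjusted p = 0.938). With adjustment over the list alone, 3 rose and 1 fell, and camera gave no call (adjusted p = 0.151). Lgr5, a marker of cycling epithelial stem cells, had 4, 5, 17 and 4 counts in M11, M12, M9 and M10 and did not pass the low-count filter. The number that rose was 0 without M11, 0 without M12, 4 without M9, 6 without M10 and 0 with all 5 libraries, and 4 fell without M9 and 1 without M10.

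Of the 30 proliferation genes tested, edgeR called 0 (3 at an unadjusted p under 0.05), DESeq2 1 lower and limma-voom 0, and adjusted over the list alone edgeR called 0. The fold change was negative for 28 of them and the median was -0.43. Mki67, which marks cycling cells, was at 186 ± 0.849 CPM alone and 141 ± 52.0 CPM in co-culture (SD, n = 2 each), a log2 fold change of -0.40 ± 0.26 (SE; adjusted p = 0.518, edgeR). Top2a was at -0.34 ± 0.27 (adjusted p = 0.587) and Ccnd1, a cyclin of the entry into the cycle, at 0.20 ± 0.21 (adjusted p = 0.696). Camera called the list lower (adjusted p = 6.14e-05; adjusted p = 0.681 with an estimated correlation), and without M10 this call was lost (adjusted p = 0.403). Without M9, 23 of the 30 genes fell, among them Mki67 by -0.82 (adjusted p = 0.00967) and Top2a by -0.78 (adjusted p = 0.0134). All 30 lay below the organoids alone in the third co-culture library, with a median of -1.96. Of 23 regulators of apoptosis and survival, edgeR called 0 (6 at an unadjusted p under 0.05; adjusted over the list alone, 0), DESeq2 1 higher and 2 lower, and limma-voom 0; Mcl1 and Bcl2l1, which restrain apoptosis, were at 0.01 ± 0.17 (adjusted p = 0.98) and -0.08 ± 0.16 (adjusted p = 0.846). Without M9 this list had 1 gene higher and 4 lower, and without M10 it had 2 higher.

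Of 12 genes of stellate cells, fibroblasts and other mesenchyme, 3 fell: Rgs5, a pericyte gene, and the collagens Col3a1 and Col6a3. Rgs5 fell from 9.15 ± 0.918 to 0.807 ± 0.454 CPM (SD, n = 2 each), a log2 fold change of -3.50 ± 0.51 (SE; adjusted p = 0.0354, edgeR). Col3a1 had 71 counts in M11 and 351 in M12, together 422, and 1 in M9 and M10 together, a ratio of 529 per total count with a 95% counting interval from 94.4 to 20939 (adjusted p = 0.0371). Col6a3 had 59 counts against 3, a ratio of 24.6 with an interval from 8 to 123 (adjusted p = 0.049). None rose, 9 did not pass, and 9 fell and 1 rose when adjusted over the list alone. The list's median was -3.35 (-1.88 without M12), or -3.10 with the 3 genes at 3 counts or fewer set to their bounds. Camera gave an adjusted p of 1.73e-05, against an adjusted p = 0.681 with an estimated correlation. In the third co-culture library 11 of these 12 genes lay below the same M11 and M12, with the list's median at percentile 0.45 of 10000 random lists matched on expression, where 11 of 28 lists lay outside the central 95%. The number that fell was 1 without M11, 0 without M12, 3 without M9, 3 without M10 and 0 with all 5 libraries, and 1 rose without M9 and 1 without M10. Rgs5 was at -4.21 without M9. The fitted log2 fold change of Col3a1, -8.63, was -9.35 without M11, -7.15 without M12, -7.80 without M9 and -10.78 without M10, and its call was lost without M12, M9 or M10, those of Rgs5 and Col6a3 without M11 or M12, and limma-voom did not call Col3a1 and Col6a3.

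Pecam1 and Cdh5, which encode endothelial adhesion proteins, had 1 and 3 counts in M11, 2 and 2 in M12, 2 and 6 in M9, 2 and 5 in M10, and 10 and 19 in the third co-culture library. Stab2, a scavenger receptor of liver sinusoidal endothelium, had 0 counts in M11 and M12, 2 in M9, 5 in M10 and 0 in the third co-culture library. Of 24 pan-endothelial genes, 10 passed the low-count filter, and 1 rose and 1 fell. Ptprb rose by 2.17 ± 0.19 (log2, SE; adjusted p = 0.0137, edgeR), from 9.22 to 41.5 CPM, and Flt4, the receptor of vascular endothelial growth factor C, fell by 2.22 ± 0.18 (adjusted p = 0.0106), from 125 to 26.9 CPM. With adjustment over the list alone, 1 rose and 3 fell. In the third co-culture library Ptprb differed from the organoids alone by 0.10 and Flt4 by -0.54. Both calls were lost without M11, without M12 and with all 5 libraries, while 1 gene of the list rose and 3 fell without M9, and 1 rose and 2 fell without M10. Of 10 liver sinusoidal endothelial genes tested, edgeR called 0 (3 at an unadjusted p under 0.05; 3 higher and 0 lower adjusted over the list alone), DESeq2 2 higher and limma-voom 0. Their median was 0.75, or 1.54 over the 7 with whole counts, 0.22 without M11, 1.55 without M12, 0.14 without M10 and -1.13 in the third co-culture library. Mrc1, a mannose receptor, was at 4.63 ± 0.88 CPM alone (SD, n = 2) and at 25.9 and 10.4 CPM in M9 and M10, a log2 fold change of 1.97 ± 0.48 (adjusted p = 0.112), and at 0.135 CPM in the third co-culture library. It passed at 1.18 without M9 (adjusted p = 0.0404), at 2.49 without M10 (adjusted p = 0.000612) and at 1.97 by DESeq2 (adjusted p = 0.00105). Il1a was at -0.31 ± 0.27 (adjusted p = 0.632). Of this list 3 rose and 1 fell without M9 and 1 rose without M10.

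Of 13 squamous and basal genes tested, 2 rose: Sprr2a1, of the cornified envelope, by 2.86 ± 0.20 (log2, SE; adjusted p = 0.0074, edgeR), and the basal keratin Krt14 by 3.63 ± 0.61 (adjusted p = 0.0491). Sprr2a1 has near-identical neighbours, so its counts are uncertain. Adjusted over the list alone, 6 rose and 1 fell, and camera gave an adjusted p of 0.008 (adjusted p = 0.681 with an estimated correlation). Both genes were also above the organoids alone in the third co-culture library, by 4.68 and 3.55, although the list's median there was -2.05. Of 16 gastric and intestinal genes, Lgals4, a galectin of intestinal epithelium, rose by 2.46 ± 0.34 (adjusted p = 0.0314), from 150.4 ± 69.0 to 830 ± 87.0 CPM (SD, n = 2 each), and was at 569 CPM in the third co-culture library, where 8 of the 16 genes lay above the organoids alone and the list's median was -0.30, against 0.79 in M9 and M10. Adjusted over the list alone, 7 of these rose and 5 fell, and camera gave no call (adjusted p = 0.216). Without M11 the calls of Krt14 and Lgals4 were lost, without M12 all 3, and without M9 or M10 that of Lgals4. Limma-voom did not call Krt14. Without M9, 4 squamous genes rose and 1 fell, against 5 and 1 without M10; of the gastric and intestinal genes 4 rose and 3 fell without M9, 3 and 4 without M10, and 0 and 1 without M11.

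Among receptors, ligands and matrix proteins, 2 of 19 growth factor genes fell, Fgfr1 and Egfr, the latter by -1.26 ± 0.17 (log2, SE; adjusted p = 0.0302, edgeR). With adjustment over the list alone, 3 rose and 2 fell. Of 17 Notch genes, the ligand Jag2 rose by 1.44 ± 0.23 (adjusted p = 0.0435) and the ligand Dll1 changed by -1.87 ± 0.27 (adjusted p = 0.0361); adjusted over the list alone, 1 rose and 1 fell. Of 22 basement membrane and integrin genes, Lama3 and Lamb2 rose by 1.25 ± 0.18 (adjusted p = 0.0345) and 1.17 ± 0.19 (adjusted p = 0.0479), and Lama4 and Itga5 changed by -3.85 ± 0.40 (adjusted p = 0.0186) and -3.44 ± 0.40 (adjusted p = 0.0217). Adjusted over the list alone, 2 of these rose and 4 fell. Axl, a receptor tyrosine kinase among 20 targets of YAP and TEAD, changed by -3.66 ± 0.54 (adjusted p = 0.0371), with no other member past the test; adjusted over the list alone, 2 fell. Against the organoids alone the third co-culture library was at -4.10 for Fgfr1, -1.30 for Egfr, -1.32 for Dll1, 1.54 for Lamb2, -3.40 for Itga5 and -5.15 for Axl, but at -0.17 for Jag2, -2.22 for Lama3 and 0.34 for Lama4, opposite to M9 and M10. Camera called none of these 4 lists (adjusted p = 0.968, 0.57, 0.0603 and 0.253). Calls of Egfr, Jag2, Dll1, Lama3, Lamb2, Lama4, Itga5 and Axl were lost without M11 and without M12, and that of Fgfr1 without M12. Limma-voom did not call Jag2 and Lamb2, nor edgeR without a low-count filter Axl. Axl was at -3.05 without M9 and -4.72 without M10, and Itga5 at -4.05 without M9. Without M9 the genes higher and lower were 5 and 4 for growth factors, 2 and 1 for Notch, 3 and 4 for basement membrane and 2 and 3 for YAP and TEAD; without M10 they were 2 and 2, 1 and 1, 2 and 6, and 0 and 3.

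**Figure D2:**
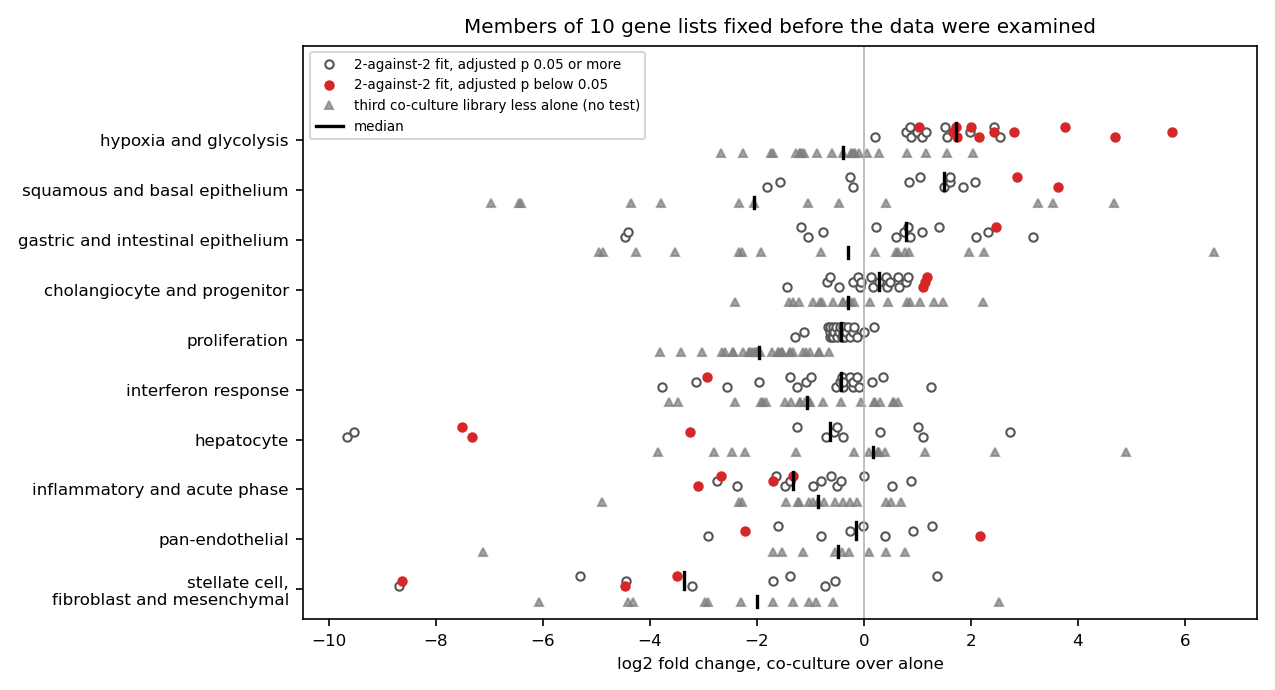
Fitted log2 fold change (co-culture over alone) of each tested member of 10 gene lists: circles are M9 and M10 against M11 and M12, filled red where the adjusted p is below 0.05, triangles are the third co-culture library less the organoids alone, without a test, and black bars are medians. All 23 glycolysis and hypoxia circles lie above 0 with a median of 1.72, whereas the triangles have a median of -0.38; fitted values of genes with 3 counts or fewer in one group, such as Col3a1, are not bounds.

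The third co-culture library did not enter the calls and was set against them. Of 349 called genes found in its table, 279 (79.9%) differed from the organoids alone in the called direction: 69.4% of the 157 higher genes and 88.5% of the 192 lower genes. Because M11 and M12 serve both comparisons, part of this is expected with no effect at all. For the same number of top genes, 20 simulations of unchanged libraries gave a mean of 84.7% and a highest value of 87.4%. The observed share of 79.9% was below both. How far offsets between annotations lower the share expected with no effect was not tested. The simulated top genes differed by noise only, part of it shared through M11 and M12. Their 84.7% need not be the level expected for the actual calls. The share therefore cannot decide whether the called directions recur. Among genes that were not called, 63.4% had the sign of the fit. In the third co-culture library the medians were 0.82 for the higher and -2.67 for the lower calls, against 2.17 and -3.59 in the fit. Over all 14319 genes compared, the covariance of the fold changes of M9 and M10 with those of the third co-culture library was 0.59, against a simulated mean of 0.10 and a highest value of 0.11. The correlation over these genes, which are not independent replicates, was 0.43, against a simulated mean of 0.42. Sharing M11 and M12 gives the simulated value by itself, and the simulated libraries carry no offsets between annotations. The likeness of these correlations therefore does not show that there is no effect. On log2 CPM the third co-culture library correlated at 0.877 and 0.876 with M11 and M12 and at 0.891 and 0.892 with M9 and M10. The organoids alone are only 2 libraries and could not be split further. Since the third co-culture library comes from another table, offsets between annotations are part of each of its differences.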

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

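The fit of genes with whole counts in all 4 libraries and the counts of list members under each fit were chosen after seeing the data. The 356 calls (158 higher, 198 lower, 346 at least 2-fold) kept their direction under each scaling, tool and filter and without each of the 4 libraries; genes with whole counts covered 269 of them. Scaling by RLE gave 360 calls and library totals 413, the filter at 10 counts 421, and genes with whole counts 335. DESeq2 called 1314 genes (633 higher, 681 lower, 1020 at least 2-fold; all 356 shared). Limma-voom called 285, 102 of them higher, and lost 15 of 49 named genes with a call, among them Lypd8 (adjusted p 0.203), Slc16a3 (0.0673), Alb (0.0757), Hp (0.218) and Ifit2 (0.0527). Without a low-count filter there were 1404 (667 higher, 737 lower, 1077 at least 2-fold; 335 shared), with 8 of the 49 lost, among them C3 (0.333), Axl (0.34) and Trf (0.273); the cause was not tested. Leaving out a library gave 0 (without M12) to 2619 (without M9) calls, 0 to 1294 higher, 0 to 1325 lower and 0 to 1736 at least 2-fold; without M11 there were 50 and without M10 1114. With 1 alone library left, the spread comes from M9 and M10 only, which differ more than M11 and M12. All 5 libraries gave 2 calls, 0 higher and 2 lower, 2 at least 2-fold (1423 genes at an unadjusted p under 0.05), with 346 of 349 calls tested keeping their sign; leaving M9 or M10 out of these gave 0 and 0 calls by edgeR (2123 and 1055 at an unadjusted p under 0.05). Camera called 8 of 28 lists, 8 to 11 when a library was left out and 8 with all 5; with an estimated correlation it called 0 (0 at an unadjusted p under 0.05) and fry called 0 (7 at an unadjusted p under 0.05; smallest adjusted p 0.196). Cholesterol synthesis was lost without M11 (adjusted p 0.241) and M10 (0.563) and turned lower with all 5 libraries (0.897); the interferon list was lost without M10 (0.113), and the squamous list with all 5 (0.39). Some uncalled genes changed sign: Sox9 (-0.58 without M9) to 0.09 without M12, 0.31 without M10 and 0.08 in 5 libraries without M10; Mcl1 (0.19 without M12) to -0.02 with library totals, -0.14 without M11 and -0.02 without M9; Bcl2l1 (-0.36 in 5 libraries without M10) to 0.04 without M9; and Ccnd1 (0.43 without M11) to -0.13 with all 5 libraries, -0.20 and -0.45 without M9 or M10 from these; the cause was not tested. The sign share in the third co-culture library was 79.7% with library totals and 80.8% for at least 2-fold calls. No paired analysis was possible because the columns carry no replicate numbers. The planned fits on log2 TPM were not run, since only the count columns were used. Lgr5, Pecam1, Cdh5 and Stab2 had too few counts for the low-count filter, and whether depth or low expression limits them was not tested.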

Other observations

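The lists of further HIF targets and of the brush border, the 3 tests on mesenchymal transcripts, the sum over 13 endothelial genes and the number of lists outside the range of random lists were chosen after the calls or values they bear on were seen; Pecam1, Cdh5 and Kdr had been looked at before they entered that sum.

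Of 22 interferon response genes, 1 fell: Ifit2, an antiviral protein, by -2.94 ± 0.48 (log2, SE; adjusted p = 0.0483, edgeR), which was lost without M11 and without M12; limma-voom did not call it either; without M9, 9 fell and without M10, 3. Adjusted over the list alone, 3 fell. Camera called the list lower (adjusted p = 0.000483; adjusted p = 0.681 with an estimated correlation), a call lost without M10 (adjusted p = 0.113). Of 19 p53 and senescence genes, Igfbp3, which binds insulin-like growth factors, fell by 1.37 ± 0.19 (adjusted p = 0.0345), also lost without M11 and without M12, and in the third co-culture library it was at -6.15. Without M9, 2 of these rose and 5 fell, against 0 and 1 without M10; adjusted over the list alone, 1 rose and 1 fell. Of 21 cholesterol synthesis genes edgeR called 0 (4 at an unadjusted p under 0.05), DESeq2 1 higher and 1 lower, and limma-voom 0, with 0 adjusted over the list alone; without M9, 9 rose, and without M10, 1 rose and 1 fell. Camera called this list higher (17 of 21 positive; adjusted p = 0.0272; adjusted p = 0.681 with an estimated correlation), a call lost without M11 (adjusted p = 0.241) and without M10 (adjusted p = 0.563), while 0 of the 21 lay above the organoids alone in the third co-culture library. In the third co-culture library the median against the organoids alone was -1.06 for the interferon list, -0.96 for the p53 list, -0.62 for the cholesterol list, 1.20 for the 13 mitochondrially encoded genes and -1.96 for the 30 proliferation genes. These were among 11 of 28 lists outside the central 95% of 10000 random lists matched on expression, so such values were common in that library. The brush border list, raised as a hypothesis from Gpa33, Myo7b and Lgals4, gave a camera p of 0.0127 at the preset correlation but 0.428 with an estimated one, and its median in the third co-culture library (0.29) was at percentile 91.12 of random lists, so a wider brush border programme was neither shown nor excluded.

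Of 23 glycolysis and hypoxia genes 11 rose in M9 and M10, a list call lost with an estimated correlation (adjusted p = 0.681), and 6 of the 23 lay above the organoids alone in the third co-culture library. Reads shared with pseudogenes, which Ldha and Pgk1 have, would not raise members whose estimated counts were whole, yet the 9 such members had a median of 2.43 in M9 and M10 and of -0.18 in the third co-culture library. Offsets between the 2 tables that fall on genes independently would leave the list's median difference between the third library and M9 and M10 among random lists. It was -2.18, at percentile 0 of 10000 random lists matched on expression. The list was followed up for being high in M9 and M10, which also lowers this difference. The percentile therefore overstates the case against such offsets as the whole cause. As 10 of 28 lists lay outside the central 95% of random lists in this difference, offsets shared by related genes stay open. Against the organoids alone the list's median in the third library was -0.38, at percentile 8.43, inside the central 95%. A wider response of hypoxia-inducible genes remains a hypothesis: the further HIF targets were higher as a set at the preset correlation (camera p = 1.22e-10) but not with an estimated one (p = 0.131). Oxygen, culture density and harvest may differ between these cultures, and no label or test separates them.

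Of 12 mesenchymal genes 3 fell in M9 and M10 and 9 did not pass, a list call lost with an estimated correlation (adjusted p = 0.681). Lower depth is argued against, as the co-culture libraries M9 and M10 had 1.25 times the mean total count of the organoids alone. Fewer mesenchymal cells could give the list's median of -3.35 (-3.10 with 3 genes at their bounds, -1.88 without M12), but so could lower expression per cell, and these cannot be told apart in bulk RNA. Passage may also be the cause, since 0 libraries of organoids alone were at passage 8, so loss of such cells over passages and co-culture cannot be told apart.

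Flt4 fell and Ptprb rose in M9 and M10, and Ecscr, named after its values were seen, was at -1.60 (adjusted p = 0.051). RNA from the endothelial cells of the co-culture was tested as a source of the Ptprb rise: 13 of the 24 pan-endothelial genes, including Pecam1, Cdh5 and Kdr, summed to 1.59 and 1.10 CPM in M11 and M12, 1.12 and 1.09 CPM in M9 and M10 and 0.99 CPM in the third co-culture library. The lower sum of M9 and M10 was 0.69 times the higher sum of M11 and M12. This sum of 13 genes thus did not rise, while Ptprb alone went from 9.22 to 41.5 CPM. These 13 leave out 11 genes, among them Flt4, Ptprb and Ecscr, and of the liver sinusoidal endothelial genes 3 were higher when adjusted over the list alone and 0 lower (median 0.75), so a share of endothelial RNA stays open, as do passage and co-culture.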
